A study of Mus musculus with 2 samples.

How the data were processed

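H3K4me1 ChIP-seq was carried out on limb tissue of B6NCrl mouse embryos at 15.5 days, in 2 biological replicates made from 78 and 62 embryos of both sexes, with a size range of 300 to 500 in the labels. The replicates came from separate pools of embryos per the labels, and so measure biological and technical spread together. There were 4 deposited peak lists: 1 for each replicate, 1 for both replicates together (here the pooled list) and the replicated list, which per the file headers was derived from the other 3. All use mm10 (GRCm38). The aligner, the peak caller, its thresholds and the rule for a replicated peak are not given in the sources used here. Both replicate lists and the pooled list were derived per the file headers from a further pair of files in common, not analysed here, so the replicate lists are not fully independent.

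Each list gives per peak a start, an end and the authors' own values, used within their list except where signal values of the replicate lists were compared. The deposited score (10 to 1000 in each list) was not used. The deposited signal value, whose reference is not stated in the file headers, was used to rank peaks and to compare strength. The −log10 p and −log10 q of each peak are as the authors deposited them, with a lowest −log10 p of 2.0, and served as filters. The deposited offset of the summit was used for 1 alternative. The files hold no read counts, so the depth of each library is unknown, and no interval that needs depth is given. With 2 replicates and no second group no p-value was computed. Errors are SDs between the replicate lists (n = 2), spreads over shifted lists or bootstrap intervals over chromosomes.

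Chromosomes 1 to 19, X and Y were kept, on which 2, 3, 6 and 2 peaks were lost from the replicate 1, replicate 2, pooled and replicated lists. Genes were taken from GENCODE vM21, with transcript starts and exons of its basic set and 21911 protein-coding symbols. Sequence, with repeats in lower case, was the NCBI assembly GRCm38.p6. Overlap of a peak meant at least 50% of its length covered by the other list. Chance was estimated by 100 circular shifts of a list within each chromosome (20 for alternatives), outside the first 3 Mb. Midpoints within 1 kb of a TSS were called promoter, then exon, intron or intergenic. TSS profiles used bins of 100 bp to 5 kb. A promoter was CpG-rich with an observed to expected CpG ratio of at least 0.75 and at least 55% G and C within 500 bp of the TSS, CpG-poor with a ratio under 0.48, and otherwise intermediate.

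For each protein-coding gene the percent of the 50 kb on each side of its TSS inside peaks was taken. Each of 18 gene lists, reduced to members over 100 kb apart, was set against 10000 random lists matched on the number of TSSs in the window, and its median called high or low at the 97.5th and 2.5th percentile. A chromosome was the unit for X and for the bootstrap of motif ratios (1000 draws) and of peak strength (200 draws). Motif matches on both strands outside repeats were counted per kb in peaks with midpoints over 2.5 kb from a TSS and in flanks of the same length on both sides outside pooled peaks. The ratio was divided by that of the reversed, not complemented, consensus, as a control of base composition; the reversed sequence can hold CpG pairs that the consensus lacks. An interval was given where at least 95% of the draws had matches to divide by, a rule added after the motif values were seen; without it CTCF would count as denser in the short gaps of the closing section.

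Genes were named by a rule fixed before the data were examined: 20 genes whatever their values, from each list the 2 members of highest and the 1 of lowest cover, the 10 genes of highest cover with windows that do not overlap, and the 5 widest and 5 highest-signal peaks. Gene lists, consensus sequences, tests and most alternatives were fixed then too. Alternatives were each replicate list alone, the pooled list, a −log10 q of at least 5, the upper 50% of peaks by signal value, other overlaps, windows and matchings, repeats kept, flanks alone, and 200 bp on each side of the summit. Leaving X genes out of the lists, and asking for 50% of a pooled peak in both replicate lists, were added after the data were seen.

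Replicate overlap, promoter share, the TSS profile, gene lists, motif ratios and the X signal factor were tested on simulated data. The other statistics were not. With 59.9% of the 202978 peaks of replicate 1 kept in place, 60.4% were recovered as overlapping. Of 6054 midpoints planted within 1 kb of a TSS 100% were called promoter. Gene lists drawn from the 21911 genes passed the upper threshold in 2.5% of cases unchanged, 38.5% with cover multiplied by 2 and 72.0% with cover multiplied by 3. For motifs, a planted ratio of 2.31 was recovered as 2.17 on average over 30 simulated genomes, with 30 of 30 intervals above 1. Of 468 intervals of consensus sequences that were not planted, 7.26% excluded 1, so the 95% intervals were somewhat too narrow there. These genomes had random bases in equal shares, with the same composition in peaks and flanks. The rate of false calls in real sequence was thus not measured. The number of genomes was raised to 30 after runs of 1 genome, in which 5 of 17 intervals excluded 1, of 10 genomes, and of 20 genomes, in which the rate was somewhat higher than here. A factor of 0.6 on 28000 simulated X signal values was recovered as 0.588. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.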

Results

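Monomethylation of lysine 4 of histone H3 (H3K4me1), a chromatin mark found at enhancers and beside promoters, was mapped by ChIP-seq in the limbs of mouse embryos at 15.5 days of development. Replicate 1 was made from the limbs of 78 embryos and replicate 2 from those of 62 embryos, male and female pooled. The labels name both as biological replicates of 1 group, so the design gives no contrast between conditions. The comparisons below are between gene groups, regions, chromosomes and replicates. The list of replicate 1 held 202978 peaks on the chromosomes (median width 291 bp, 86.4 Mb covered), that of replicate 2 held 204765 (332 bp, 102.2 Mb), and the list made from both together held 233426. Of these, 140910 peaks covering 96.3 Mb were in the authors' replicated list, which was used throughout unless another list is named.

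The first comparison asked which gene groups lay in chromatin rich in H3K4me1. Limb patterning regulators had the highest cover of the 18 gene lists. The median member had 13.8% of the 50 kb on each side of its TSS inside peaks, 4.98 times the median of random lists, and 31 of the 34 members with separate windows lay above the median gene. Chondrocyte genes (9.27%, 2.77 times), tendon, joint and connective tissue genes (8.41%, 3.00 times), skeletal muscle genes (8.46%, 2.73 times) and osteoblast genes (10.6%, 3.03 times) followed by percentile, while housekeeping and heart genes, given below, lay among them by median cover. These 5 lists of limb tissues lay at the 100th, 99.8th, 99.7th, 99.7th and 99.0th percentile of 10000 random lists matched on gene density, and above the upper threshold of the test in each replicate list as well. The osteoblast list fell below it with windows of 20 kb (90.2) and 100 kb (92.3) on each side.

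Among the patterning genes, the homeobox gene Prrx2 of limb mesenchyme (chromosome 2, 30834972 to 30881251) had 42.5% of its window covered (39.8% ± 2.91 in the separate lists, SD, n = 2), and its relative Prrx1 had 17.7% (15.8% ± 2.73). Hoxa9 reached 35.3% (33.0% ± 3.84). The digit genes Hoxa13 (chromosome 6, 52257694 to 52260880) and Hoxd13 (chromosome 2, 74668310 to 74671599) had 27.8% (26.5% ± 2.95) and 26.1% (25% ± 3.04). Tbx4 and Pitx1, which act in the hindlimb, had 29.0% (27.5% ± 5.25) and 19.5% (16.9% ± 2.09), and the forelimb gene Tbx5 had 18.6% (17.9% ± 1.54). The Hedgehog effector Gli3 had 15% (13.9% ± 2.28). Cover varied within the list: Shh, the morphogen of the posterior margin, had 5.18% (5.58% ± 0.853), the BMP antagonist Grem1 3.55% (3.61% ± 0.322), and Fgf10, the lowest of the list, 1.49% (1.32% ± 0.515). The median over all 21911 protein-coding genes was 4.09%, with 4146 genes at 0.

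In the skeletal lists, Pth1r, the receptor for parathyroid hormone and its related protein, had 38.2% (34.0% ± 1.99), the cartilage matrix gene Comp 33.8% (32.5% ± 0.835) and the cartilage collagen gene Col2a1 20.7% (19.9% ± 3.75), while Col11a1 had 0.778% (1.54% ± 0.218). Sox9, the regulator of chondrocyte fate, had 10.4% (9.42% ± 1.43). Col1a1, the main collagen of bone, had 33.5% (29.0% ± 4.00) and the osteoblast factor Sp7 21.3% (19.5% ± 1.16). Runx2 had 2.66% (2.98% ± 0.150), below the median gene, and Dmp1 of mature bone cells 0 in the replicated list (0.274% ± 0.387). A window is centred on the outermost TSS of its gene. Other promoters of a long gene such as Runx2 (chromosome 17, 44495987 to 44814797) can thus lie outside it. The tendon factor Scx had 22% (21.5% ± 1.6), Tcf7l2 32.2% (29.5% ± 3.73), Fmod 27.0% (26.3% ± 5.30) and the joint gene Gdf5 9.24% (10% ± 1.96), whereas Tnmd, which lies on X, was at 0 in every list. In skeletal muscle the fast troponin gene Tnnt3 had 52.7% (49.7% ± 0.259) and the slow troponin gene Tnni1 28.9% (27.8% ± 0.133), against 3.41% (3.91% ± 0.437) for the regulator Myod1 and 0.308% (0.582% ± 0.0184) for the myosin gene Myh8. The window of Tnnt3 overlaps that of its neighbour Mrpl23, so its value is that of the locus.

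Of the lists of cells that accompany these tissues, epidermis lay at the 96.1st percentile (median 8.36%), endothelium at the 83.9th, Schwann cell and melanocyte at the 81.6th, macrophage and leukocyte at the 49.9th and erythroid at the 15th, none beyond a threshold, though epidermis passed with windows of 20 kb (99.7). Grhl3 (26.3%) and Tfap2a (14.8%) led the epidermal list, while the basal keratinocyte genes Krt14 and Trp63 had 1.65% (2.30% ± 0.8) and 0.407% (0.816% ± 0.417). Trp63 (chromosome 16, 25683763 to 25892102) extends far beyond its window, so its value leaves out any promoter further inside the gene. Endothelial Egfl7 had 20.2% and Erg 16.8%, against 3.72% (4.09% ± 0.366) for the endothelial cadherin Cdh5 and 0.25% for Emcn. Cd68 (19.4%) and Aif1 (14.6%) led the macrophage list and Adgre1 was at 0. Epor (14.4%) and Klf1 (13.4%) led the erythroid list, with X-linked Alas2 at 0. Sox10 (13.7%) and Pmel (10.1%) led the Schwann and melanocyte list, with Cdh19 at 0.

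Lists named for other organs were mixed, and whether their genes are also active in the limb was not examined. Heart genes lay at the 98.4th percentile (median 9.41%, 2.65 times random), led by Myl7 (20.4%) and Tnni3 (13.2%) with Ryr2 lowest (1.97%). Forebrain and neuron genes lay at the 98.1st (6.25%, 2.32 times), led by Neurod2 (21.4%) and Dlx2 (14.5%), with Neurod1 at 3.16% (3.12% ± 0.133) and Syt1 lowest (1.22%). Gut and pancreas (94.1st percentile, Cdx1 23.2%, Vil1 11.3%, Cftr 0.242%), photoreceptor and retina (71.5th, Gnat1 45.3%, Rho 18%, Rpe65 at 0), germ cell (65.4th, Prm1 24.7%, Prm2 21.0%, Sycp1 at 0), kidney (62.0th, Pax2 12.5%, Six2 11.7%, Umod at 0) and hepatocyte (26.1st, Apoa2 18.1%, Foxa3 15.9%, Afp and Alb at 0) did not pass, though gut and pancreas did in the upper 50% of peaks by signal value (98.4). Housekeeping genes lay at the 95.8th percentile (10.2%), from 34.8% for Rplp0 and 22.9% for Rpl13a to 0 for X-linked Hprt, and passed with windows of 20 kb (99.9). A window holds the peaks of neighbouring genes too, so the value of a gene such as Gnat1 is that of its locus. The same holds for genes of the limb lists, such as Hoxa9 and Hoxa13, whose windows overlap. In all, 7 lists passed the upper threshold and 0 the lower, against 0.45 expected in each tail for genes drawn at random. The random lists came from all 21911 protein-coding genes, 4146 of them at 0. All lists of other organs but hepatocyte lay above the middle of the random lists. The 0.45 is thus not the count expected for lists of chosen, well-studied genes. The forebrain list fell to the 93.9th and 96.9th percentile in the replicate lists, to 70.9 by number of peaks, 82.1 without matching, 83.5 with windows of 100 kb, 94.9 in the pooled list and 97.0 without X genes. The heart list fell to 91.2 by number of peaks, 96.3 with windows of 100 kb and 95.7 with all members kept. With random lists not matched on gene density only the limb patterning and chondrocyte lists among these 7 still passed, the housekeeping list passed at 98.0, and the tendon, skeletal muscle, osteoblast and heart lists had 95.2, 95.5, 96.8 and 95.4.

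**Figure D1:**
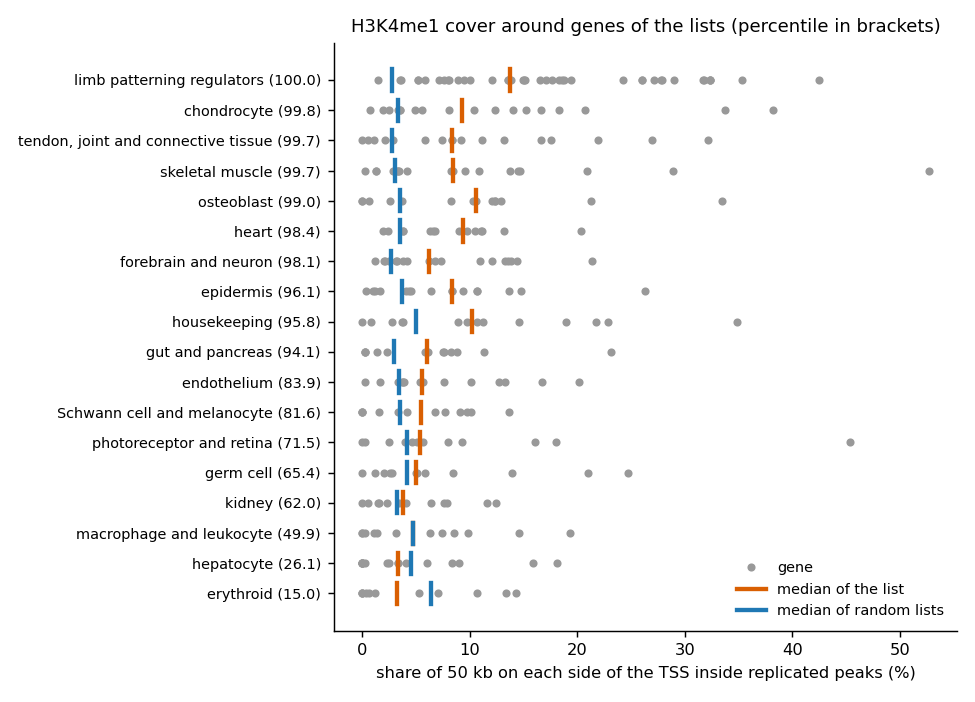
Each grey point is a gene, placed by the percent of the 50 kb on each side of its TSS inside replicated H3K4me1 peaks (horizontal axis), in rows by gene list. Orange bars mark the median of the members with separate windows and blue bars that of matched random lists, with the percentile in brackets; limb patterning regulators are at the top with a median of 13.8%.

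Among windows centred on protein-coding TSSs, with overlapping ones left out, those of highest cover held genes of several kinds. The highest window, at G430095P16Rik on chromosome 8 (70.0% covered, 67.2% ± 3.25), includes part of Nfix, a nuclear factor I gene. The windows of Ncor2, a nuclear receptor corepressor (61.2%, 58.6% ± 0.574), Ski, a repressor of TGF-beta signalling (60.6%, 56.9% ± 3.58), Mrpl23 (60.3%, 57.3% ± 1.04), Gse1 (55.3%, 52.7% ± 1.25), the retinoid receptor gene Rxra (55.3%, 52.3% ± 3.18), Dusp7 (54.2%, 51.5% ± 3.54), Synpo (54.1%, 50.6% ± 6.05), Dohh (53.0%, 50.6% ± 1.58) and the collagen gene Col5a1 (52.0%, 48.8% ± 2.0) completed the first 10; Tnnt3, above Col5a1, was left out because its window overlaps that of Mrpl23. The differences between replicates at these genes were smaller than their distance from the 95th percentile of all genes, 23.8%.

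The widest peak, 18237 bp, lay in introns of Nfix (chromosome 8, 84729409 to 84747645). The peak that overlapped it most was 5614 bp in replicate 1 and 19287 bp in replicate 2, so its rank as a single peak rests on replicate 2. In replicate 1 96.7% of it was covered all the same, by several peaks. For the peaks below, too, the replicate widths are those of the peak with most overlap. They do not give the width of the covered zone. The Nfix peak was followed by a peak of 16461 bp in Nfic (chromosome 10, 81405974 to 81422434), another nuclear factor I gene. A peak of 14709 bp lay in Pmepa1 (chromosome 2, 173252857 to 173267565; 6473 and 7660 bp in replicates 1 and 2), and peaks of 14510 and 13510 bp in Ahdc1 (chromosome 4, 133013038 to 133027547, 7421 and 14499 bp, and 133039956 to 133053465, 14065 and 8413 bp). By their midpoints all 5 were intronic, and at least 96.0% of each was covered in both replicate lists. The highest signal value, 11, was at an intronic peak of Gse1 (chromosome 8, 120263163 to 120272251). The peak with most overlap had 4.64 in replicate 1 (6042 bp wide) and 10.8 in replicate 2 (9068 bp), and need not be the strongest one there. A peak in an intron of Bop1 beside Scx (chromosome 15, 76459508 to 76467449) and the wider Ahdc1 peak both had 10.7, a peak at the promoter of Phf21b (chromosome 15, 84854036 to 84855864, midpoint 1099 bp from the protein-coding TSS) had 9.93, and an intronic peak of Bcl9l, a gene of the Wnt pathway (chromosome 9, 44492412 to 44498782), had 9.83.

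A further comparison set the position of peaks against circularly shifted copies of the same list. Introns held most peaks, with 52.8% of midpoints against 42.4% after shifting, and regions between genes held 26.7% against 50%. Promoters, within 1 kb of a TSS, held 15.7% against 4.49% (range 4.23% to 4.85% over 100 shifts), 3.5 times as many, and exons 4.72% against 3.10%. In the replicate lists the promoter share was 14.2% for replicate 1 and 13.6% for replicate 2, both above the highest shifted value. The median peak lay 9.54 kb from the nearest TSS, 49.0% lay over 10 kb away and 11.9% over 50 kb away.

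Around protein-coding TSSs the mark formed a pair of flanking zones. At the TSS 20.4% of positions were inside a peak, against 35.2% at 900 to 1000 bp downstream and 26.5% in the highest upstream bin, and 6.63% near 5 kb. The TSS value was thus 0.580 of the highest value (0.602 in replicate 1 and 0.560 in replicate 2). CpG-rich promoters, typical of broadly expressed and developmental genes, carried this shape: their 5417 TSSs had 14.3% of positions covered within 100 bp and 36.6% at 1 to 2 kb. The 9883 CpG-poor promoters, typical of tissue-restricted genes, had the opposite order, with 17.1% within 100 bp and 7.09% at 1 to 2 kb. The 6611 intermediate promoters had 30.5% and 26.9%. The order was the same in each replicate list for CpG-rich (13% and 31% in replicate 1, 13.4% and 36.7% in replicate 2) and CpG-poor promoters (15.4% and 6.36%, 16.8% and 7.11%).

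**Figure D2:**
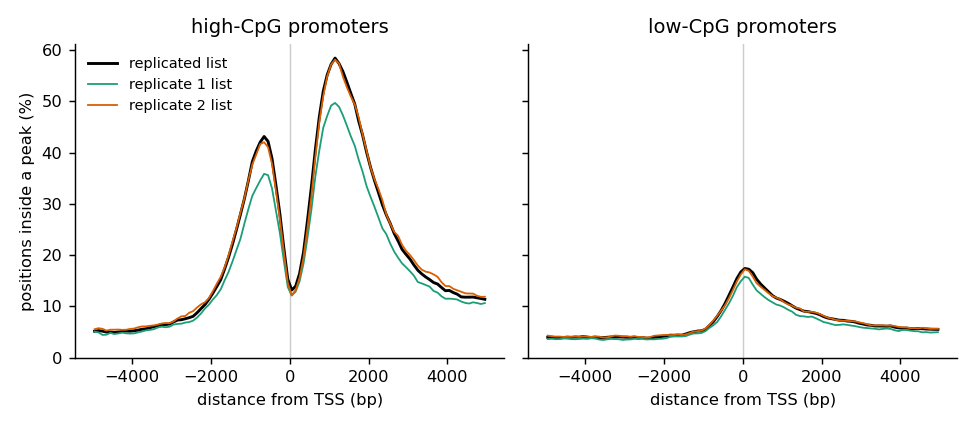
Percent of positions inside an H3K4me1 peak (vertical axis) by distance from the TSS in bp (horizontal axis, transcription to the right), for high-CpG (left) and low-CpG promoters (right); lines are the replicated list and each replicate list. High-CpG promoters dip at the TSS between flanks that reach 43.1% upstream and 58.4% downstream, and low-CpG promoters have a low single summit at the TSS.

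Sequence motifs were compared between the 102113 distal peaks, with midpoints over 2.5 kb from any TSS, and their flanks. Of 18 consensus sequences fixed beforehand, 13 were denser in peaks than in flanks relative to their reversed sequence, and 12 of these in both replicate lists too. The E-box CAGCTG bound by myogenic factors was 1.67 times denser (95% interval 1.54 to 1.80), MEF2, also of muscle, 1.67 (1.51 to 1.86), PBX-HOX 1.54 (1.44 to 1.63) and the TWIST-type E-box CATCTG, of mesenchyme, 1.40 (1.37 to 1.44). TEAD (1.22), AP-1 (1.2), posterior HOX (1.2), RUNX of bone and cartilage (1.17), TP63 of epidermis (1.14), homeobox (1.12), MEIS (1.10) and GATA (1.04) were closer to 1, with intervals above it, but RUNX had 0.973 (0.942 to 1.01) with repeats kept and 1.01 (0.984 to 1.03) against flanks alone. HNF1, a liver and kidney factor, had 3.58 (1.56 to 7.76) from 26 matches in peaks, and its interval included 1 in each replicate list. SOX (0.985), ETS (1.06), HNF4 (1.05), NFI (2.36, interval 0 to 11) and CTCF (0.669, 0.358 to 1.21) had intervals that included 1. ETS was denser in replicate 2 (1.16, 1.04 to 1.30), and CTCF was sparser in replicate 1 (0.473, 0.308 to 0.742) and the pooled list (0.577, 0.348 to 0.982). Against flanks alone, with no reversed sequence, homeobox, posterior HOX, PBX-HOX, GATA, MEF2 and HNF1, which are rich in A and T, fell on the other side of 1 (0.546 to 0.923), and NFI (3.10, 2.39 to 4.14), ETS (1.39, 1.29 to 1.49), SOX (0.856, 0.834 to 0.878) and CTCF (0.668, 0.622 to 0.725) had intervals that excluded 1. Within 200 bp of the summit CTCF had 1.19 (1.12 to 1.26) against flanks alone. These windows were not cut at the peak ends, and 51.5% of all replicated peaks were under 500 bp wide. They can thus hold sequence outside the peaks, so this value does not place CTCF matches inside them. AP-1 (1.09), TEAD (1.15), both E-boxes (1.73 and 1.16), MEIS (1.07) and TP63 (1.03) were above 1 by both measures, with intervals above 1.

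**Figure D3:**
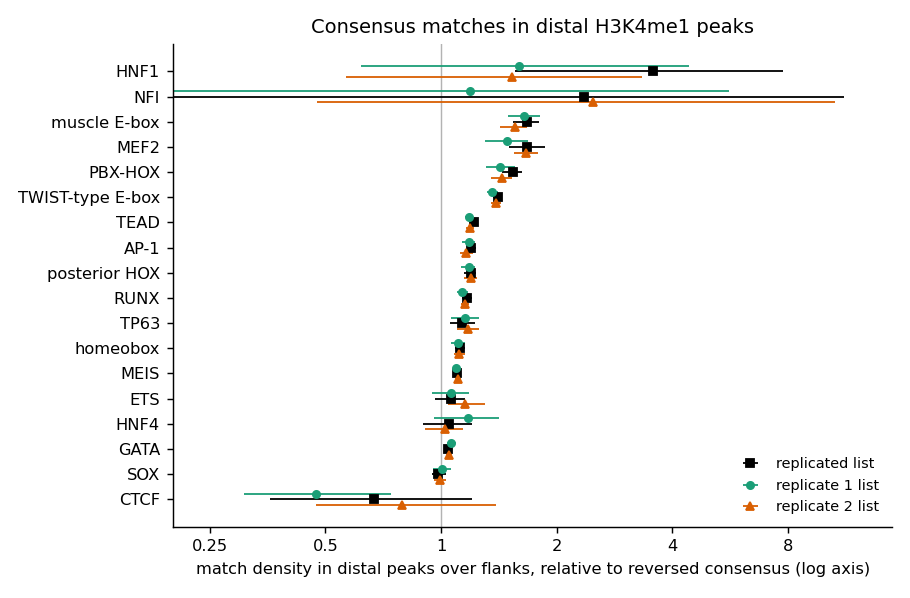
Density of consensus matches in distal peaks over flanks, divided by the same ratio for the reversed consensus (horizontal log axis), for the replicated list and each replicate list. Bars are 95% intervals over chromosomes, drawn from 0.2 upwards; the muscle E-box stands at 1.67 and GATA at 1.04.

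Chromosome X carried far fewer peaks than any autosome. It had 4.64 peaks per Mb against 57.5 ± 10.2 (SD over 19 autosomes), 12.4-fold fewer, and the sparsest autosome, chromosome 3, had 41.4. The densest was chromosome 11 with 86.3, which holds Tbx4 and Col1a1. The X value was 6.66 per Mb in replicate 1 and 7.5 in replicate 2, against autosomal means of 82.7 and 83.4. A peak lay within 1 kb of the TSS of 14.0% of the 948 protein-coding genes of X, against 63.3% ± 5.96 on autosomes. The list members Tnmd, Alas2 and Hprt, at 0 above, lie on X. Chromosome Y held 1 peak, in the list of replicate 1 alone.

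**Figure D4:**
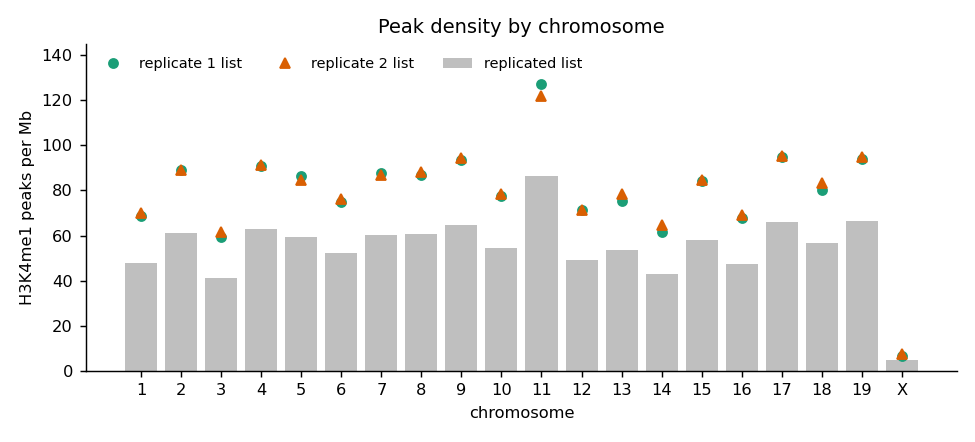
H3K4me1 peaks per Mb (vertical axis) on each autosome and X. Bars are the replicated list and points the lists of replicates 1 and 2; X stands at 4.64 in the replicated list and the lowest autosome at 41.4.

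Genes with much H3K4me1 in one replicate had much in the other: across the 21911 genes, which are not independent of each other, the covered share had a Spearman rho of 0.989 between replicates. Single peaks were less alike. Of the peaks of replicate 1, 61.6% were covered over at least 50% of their length in replicate 2, and 50.2% the other way, against 4.19% and 3.42% after shifting. The share went from 39.2% in the lowest of 5 classes of replicate 1 by signal value to 92.8% in the highest, and from 25.9% to 86.9% in replicate 2. Shared sequence came to 60.3 Mb, 69.8% of the bases of replicate 1 and 59.0% of those of replicate 2. Where both replicates had a peak under a replicated peak (118488 peaks), their signal values had a Spearman rho of 0.530 (0.472 to 0.580 on single autosomes), and 90.1% differed by less than 1.5-fold. Replicate 2 had wider peaks, with 197 over 5 kb against 90 in replicate 1.

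The replicated list held 60.4% of the pooled peaks and 81.8% of their bases. Its peaks were stronger than the 92516 left out, which a list of recurring peaks would tend to give in any case. The median signal value was 3.06 against 2.34 (1.31 times, 95% interval over chromosomes 1.31 to 1.32) and the median width 486 bp against 208 bp. The interval does not measure the spread between replicates. From a −log10 p of 2 to 3, 7.88% of pooled peaks were in the list, from 6 to 10, 82.6%, and over 20, 100%. Of the replicated peaks, 84.1% shared at least 1 bp with peaks of both replicate lists, 15.5% with those of a single one and 0.452% with neither. By the stricter overlap defined in the methods, 71.0% of the replicated peaks overlapped peaks of both lists. With 1 bp of overlap in both lists as the rule, the replicated share of the pooled peaks was 51.5%.

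**Figure D5:**
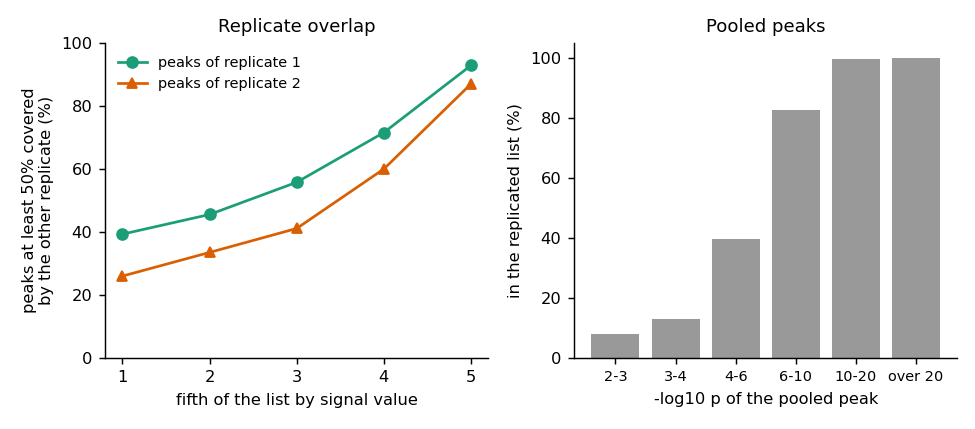
Left, percent of peaks at least 50% covered by the other replicate's peaks (vertical axis) in 5 classes by signal value, from 39.2% to 92.8% for replicate 1 and 25.9% to 86.9% for replicate 2. Right, percent of pooled peaks in the replicated list (vertical axis) by −log10 p, from 7.88% to 100%.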

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

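Outside the chromosomes used for the comparisons, the pooled list held 6 peaks on unplaced or unlocalised sequences of the assembly, above the limit of 3 that a count of 0 allows, while the replicate 1, replicate 2 and replicated lists held 2, 3 and 2. Since every list holds some such peaks and nothing sets 0 as the expected count, no reading is attached to this. With 2 samples in 1 group, samples were not tested for outlying values and no effects of groups were compared.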

How the results depend on the processing

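The direction of the overlap, promoter, strength and X results was kept under every alternative run, and 60 of 93 alternative values of the main results stayed within the spread between replicates or 1.5 times a count. The cause of the other changes was not tested. The replicated share of pooled peaks was 51.5% with 1 bp of overlap in both lists, 95.1% at −log10 q of at least 5 and 42.9% with 50% covered in both lists, an alternative chosen after the data were seen. Signal agreement was 0.604 for peaks with reciprocal overlap and 0.589 as Pearson r of log2 values. The TSS dip was 0.662 for isolated TSSs. CpG-rich cover within 100 bp was 13% to 13.4% without 1 replicate, 15.2% in the pooled list, 13.2% at −log10 q of at least 5 and 12.3% in the upper 50% by signal; at 1 to 2 kb it was 31% to 36.7% without 1 replicate and 29.9% in the upper 50%. CpG-poor cover was 15.4% to 16.8%, 19%, 14.5% and 12.7% in the same order within 100 bp, and 6.36% to 7.11%, 8.08%, 6.10% and 5.47% at 1 to 2 kb. The X chromosome density, as a ratio to autosomes, was 0.0805 to 0.0899 without 1 replicate, 0.0963 in the pooled list, 0.0588 at −log10 q of at least 5, 0.0515 in the upper 50% and 0.0579 by covered bases per Mb. The number of gene lists past the upper threshold was 4 with windows of 100 kb and 3 without matching. The number of motifs denser in peaks was 8 against flanks alone; that of sparser motifs, 0 in the main analysis, was 0 to 1 without 1 replicate, 1 in the pooled list, 1 with repeats kept and 8 against flanks alone. Homeobox (0.646), posterior HOX (0.885), PBX-HOX (0.724), GATA (0.669), MEF2 (0.923) and HNF1 (0.546) turned round against flanks alone, where base composition is not removed. Among single gene lists 16 of 198 values lost a call and 4 gained one; among single motifs 4 of 144 lost one and 8 gained one. Of the values of single named genes 420 moved and 161 did not, so percentages of single genes depend on these choices.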

Other observations

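The tests of gene families and Hox regions below, and those of the heart and forebrain lists each alone, were chosen after the results had been seen. The other tests of explanations were fixed before their values were seen, except that the CTCF density in gaps of the replicated list was already known. Several gene families, some of whose members are in the gene lists, stood in covered chromatin. Wnt ligands had a median of 12.9% of the window inside peaks, 4.59 times matched random lists (10.8% and 14.7% in the replicate lists), led by Wnt11 and Wnt9a, and Frizzled receptors, through which they signal, 9.57% (3.33 times). T-box factors had 16.2% (4.61 times), semaphorins, which guide axons and vessels, 13% (3.51 times), laminins 10.6% (3.23 times), collagens 8.13% (2.74 times), SOX factors 7.90%, forkhead factors 7.45% and integrins 7.19%, each at or above the 98.8th percentile, as were ribosomal protein genes (9.87%). Fibroblast growth factors (4.68%), bone morphogenetic proteins (4.41%), ADAMTS proteases (4.57%), nuclear receptors (7.0%) and keratins (5.77%) did not pass. Chemosensory genes were nearly bare of called peaks: 948 of 1092 olfactory receptor genes and 303 of 326 vomeronasal receptor genes had no replicated peak in their window. Many of these windows overlap, and 276 and 161 genes remained when reduced to members over 100 kb apart. How well reads can be placed in these regions was not examined, so absence of the mark is not shown. In all 10 of 17 families were high and 2 low, against 0.425 expected in each tail. That expectation holds for random lists from all protein-coding genes, the chemosensory ones among them, and not for other chosen families. Matched on promoter class too, ribosomal protein genes (93.4) and SOX factors (93.3) fell below the threshold and nuclear receptors (98.1) passed it.

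The Hox clusters differed in cover. The Hoxa cluster (chromosome 6, 52155590 to 52260880) was 39.4% inside replicated peaks (36.6% ± 4.89 in the separate lists, SD, n = 2) and the Hoxd cluster (chromosome 2, 74668310 to 74765142) 30.9% (30.2% ± 3.51), against 24.8% (24.1% ± 0.889) for Hoxc and 15.4% (14.2% ± 0.546) for Hoxb. In Hoxd, the part with paralogues 9 to 13 had 38.9% ± 5.32 and the rest 25.1% ± 1.94. In Hoxa the order was the other way, 29.7% ± 3.22 and 39.8% ± 5.69. So it was in Hoxb (9.21% ± 0.384 and 19.4% ± 1.46) and Hoxc, where the parts overlap (22.5% ± 1.88 and 26.9% ± 0.333). The part with paralogues 9 to 13 spans 82.3 kb with 2 genes in Hoxb, against 31.9 kb with 5 genes in Hoxd. The whole Hoxb cluster spans 173.9 kb, against 96.8 kb for Hoxd. The shares thus compare regions of unlike gene density.

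For the few peaks on X, 3 technical explanations were tested. No biological one was tested, and the sexes could not be compared, since each replicate pooled male and female embryos. Gene content argued against itself as the whole cause: on the line of autosomal peak density against protein-coding TSSs per Mb, X lay 6.50 residual SDs too low. Repeat content did too, since per Mb outside repeats the X density was still 0.103 of the autosomal mean, below every autosome in all 3 lists compared. A lower copy number of X in mixed male and female tissue stays open: multiplying autosomal signal values by 0.541 to 0.586 in the replicate lists would give the X density above signal values of 3, 3.5 and 4, within the range of 0.5 to 1 set beforehand but near its male-only end. The mix of sexes is not given, and the range of 0.5 to 1 admits any mix. The reference of the signal value is not stated either, so whether copy number enters it is unknown. This test thus cannot decide, and the lower dose of X was not told apart from a real difference in the mark on X.

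CpG-rich promoters were tested as the source of the high cover at limb patterning genes, since 32.4% of these have such promoters. Matched on promoter class and gene density, the list stayed at the 100th percentile in the replicated list and both replicate lists, which argues against this explanation. For the heart and forebrain lists the lower of the 2 percentiles was 98.6 in the replicated list. The heart list has 0 members with such promoters, which itself argues against this explanation for it. It stayed at or above the percentile of 99.4 in all 3 lists. With 0 such members the matching could hardly lower the percentile, so it adds no further test. The forebrain list, with 5.88% of members, had 95.2 and 97.4 in the replicate lists. It lay below the threshold there before this matching too, so the bound set beforehand, staying above the threshold in every list, did not test the explanation. Its percentile did not fall on this matching. It rose by at least 2.08 SDs of the random draws in each of the 3 lists, narrowly past the 2 asked for. These SDs measure only the error of the draws and shrink with more of them. With so few CpG-rich promoters in the list a fall was unlikely from the start, so no conclusion is drawn for it. So matched, 8 of the 18 lists passed, epidermis among them (97.6), and 6 in both replicate lists too; housekeeping fell to 88.3.

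It was asked whether factor motifs lie in the short gaps of 50 to 500 bp between adjacent distal peaks (29902 gaps) and not in the peaks. The hypothesis that short gaps between adjacent peaks hold the motifs was not borne out: 0 of the 18 consensus sequences were denser in gaps relative to the reversed sequence with an interval above 1, and 6 were sparser. By plain density homeobox (2.10), PBX-HOX (1.97), MEF2 (1.70), GATA (1.57) and posterior HOX (1.48) were denser in gaps with intervals above 1, but so were their reversed sequences (1.42 to 2.35). CTCF, singled out after its values were seen, was 4.18 times denser in gaps than in the adjacent peaks (95% interval 3.3 to 5.14; 4.33 in replicate 1 and 3.45 in replicate 2), while its reversed sequence had 0.791, with too few matches for an interval on their ratio. A candidate explanation is a CTCF site between marked nucleosomes. If so, matches would sit centrally, and 39.2% of the 181 matches were centred in the middle 33.3% of their gap (Wilson 95% interval 32.4% to 46.5%) as against the same 33.3% for even spread. That is below the 40% set beforehand as speaking against the explanation, but by less than its interval, and short of the 50% it needed, so the explanation was not borne out and is not excluded.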
